A study of Homo sapiens with 11 samples.

How the data were processed

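RNA was measured by sequencing in MIA-PaCa2, an established human pancreatic cancer cell line, after transfection of 30 nM small interfering RNA (siRNA) with RNAiMax. The labels put 4 libraries in the group given a control siRNA (siCTRL), 4 in the group given siRNA against HuR (siHuR) and 3 in the group given siRNA against YAP1 (siYAP1, replicate numbers 2, 3 and 4). HuR is the protein made from the ELAVL1 gene. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The design text names both quadruplicate and triplicate libraries, and the number of libraries used here is the number with files.

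The authors deposited an estimated count and a TPM value for each of 60554 Ensembl gene IDs in each library. Per the submitters' processing notes, the tools were CASAVA, bcl2fastq, Trim Galore 0.6.3 and kallisto 0.44.0, with genome build GRCh38.p5. Kallisto assigns reads to transcripts by pseudoalignment, so reads shared between near-identical genes are split by an estimate. The deposited estimated counts per gene were not scaled, while the deposited TPM values were scaled by the authors for transcript length and to a fixed sum per library. The annotation release, the filters and the way transcripts were added up to genes are not given in the sources used here. Gene symbols, positions and 3' UTR sequences were taken from GENCODE 29 on GRCh38, in which 56996 of the deposited IDs were found. Of the tested IDs, 17474 were found there and 13424 were protein-coding.

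Total estimated counts ranged from 35.9 to 42.9 M per library. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The main test used TMM scaling, genes kept by filterByExpr with a minimum count of 10, a robust quasi-likelihood fit of all 11 libraries with group as the only term, and Benjamini-Hochberg adjustment over the 17658 genes kept, with a threshold of 0.05. The common biological coefficient of variation was 0.275. CPM values in the text are TMM-scaled, errors beside CPM are standard deviations (SD), and errors beside log2 fold changes are standard errors (SE). The adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. The same model was tested on a single simulated data set of 17658 genes, without an effect of the replicate number. Known changes were given to genes with a mean of at least 1 CPM, 67 each at 1.5-fold and 2-fold and 66 at 4-fold in each knockdown. For siHuR against siCTRL it recovered 14.9% of 1.5-fold, 67.2% of 2-fold and 92.4% of 4-fold changes, and 3.33% of its calls were false. For siYAP1 against siCTRL it recovered 16.4%, 56.7% and 90.9%, and 1.8% of its calls were false.

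Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists within a comparison. The lists covered YAP/TAZ target genes, Hippo pathway components, reported HuR target mRNAs, AU-rich element (ARE) binding proteins with the ELAVL family, DNA replication, mitosis, DNA repair, p53 targets, apoptosis regulators, immediate early genes, inflammatory cytokines and chemokines, interferon response, unfolded protein and ATF4 response, NRF2 and oxidative stress, hypoxia response, glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, TGF-beta targets, epithelial-mesenchymal transition, integrins and focal adhesion, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones, and markers of fibroblasts, of macrophages and leukocytes, and of pancreatic acinar and endocrine cells. Members and tests were fixed before the data were examined, as were the main model, the alternatives listed here and the rule for named genes. Which lists are described beyond their test, namely those past the threshold plus the YAP/TAZ, HuR target and interferon lists, was settled after the list results had been seen.

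The rule named ELAVL1 and YAP1, then the 10 largest rises and 10 largest falls in each comparison with siCTRL (5 each way in siHuR against siYAP1). These were taken among protein-coding genes past the threshold with a mean of at least 5 CPM and with every treated library on the same side of every other library. It also took up to 4 members with the smallest adjusted p from each list described, a fixed set of YAP/TAZ targets (CCN1, CCN2, ANKRD1, AXL and AMOTL2), and up to 10 genes past the threshold in both comparisons with siCTRL. The 2 genes with opposite directions were all that existed of the 5 sought. ANKRD1 did not pass the filter on low counts and was not tested.

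Replicate numbers are shared between groups, and the labels do not say what they mark. The correlation of same-numbered libraries' deviations from their group means was 0.46, 0.24 and 0.15 between siYAP1 and siCTRL, and 0.48, 0.55 and 0.25 between siHuR and siYAP1, so in these comparisons the numbers were taken to pair the libraries. A fit with the replicate number as a block was planned as an alternative, and in these paired comparisons its value stands beside a result where it changed the call. There the block fit also left out siCTRL 1 and siHuR 1, whose number no siYAP1 library has. A changed call can therefore come from the block or from the libraries left out. For siHuR against siCTRL the block fit kept every library, and its effect is given with the alternatives. Libraries of the same group differed by more than sampling noise in every pair, with chi-square values of 24.3 to 206 per degree of freedom, so none were merged. This does not show that they came from separate cultures. Both comparisons with siCTRL use the same control libraries. Unchanged groups were therefore simulated against them in 20 data sets, and the controls were also divided into 2 pairs of libraries in all 6 ways.

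The alternatives covered other scalings (DESeq2 size factors, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, and limma on log2(TPM + 1) or log2(TPM + 0.1) for genes with a mean TPM of at least 1. They also covered other filters on low counts, a transcript length offset, fits of only the 2 groups compared, a fit that was not robust, other thresholds, and leaving out each library in turn. The counts were also computed without siHuR 3 and siYAP1 3, and without genes that carry certain 3' UTR heptamers. Both were chosen after seeing the data. The heptamer restriction removed only genes found with a word, so genes whose 3' UTR was not searched were kept, in counts and in lists.

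The heptamer search was exploratory. It scored 16163 words of 7 nucleotides for the shift in log2 fold change of genes with the word in the annotated 3' UTR of 1 transcript per gene, over 11460 protein-coding genes with a mean of at least 1 CPM and a 3' UTR of at least 30 nucleotides. Fold changes were limited to a log2 size of 3, and 3' UTR length, GC content and expression were fitted. Permutation p-values used 10000 permutations of genes, which are not independent replicates, and cannot go below 0.0001. Single values were compared between groups by two-sided exact permutation tests, for which the smallest possible p is 0.029 with 4 against 4 libraries and 0.057 with 3 against 4. Dixon ratios of list medians used unrounded values, a choice made after rounding had produced ties. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.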

Results

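RNA from MIA-PaCa2 cells, an established human pancreatic cancer line, was sequenced after siRNA transfection, and each library gave an estimated count per gene. The siCTRL and siHuR groups held 4 libraries each and the siYAP1 group held 3. Total estimated counts were 36.2, 35.9, 42.4 and 39.7 M in siCTRL 1 to 4, 37.3, 37.1, 42.9 and 40.7 M in siHuR 1 to 4, and 39.0, 42.0 and 37.3 M in siYAP1 2 to 4. The number of genes with a count was 20639 in siYAP1 3 and between 23925 and 28510 in the other libraries. Mitochondrial genes took 1.88% ± 0.574 of counts in siCTRL (SD, n = 4), 3.52% ± 1.63 in siHuR (n = 4; exact permutation p = 0.086) and 4.63% ± 2.04 in siYAP1 (n = 3; exact permutation p = 0.114). These tests were unpaired. The siHuR test did not pass 0.05, and the siYAP1 test could not, since its smallest possible p is 0.057. Within each replicate number siHuR and siYAP1 lay above siCTRL.

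The targeted mRNAs were lower in the groups labelled for them. ELAVL1, which encodes HuR (ENSG00000066044.13, chromosome 19, 7958579 to 8005659), was at 21.8 ± 9.55 CPM in siHuR and 220 ± 12.5 CPM in siCTRL (SD, n = 4 each), a 10.1-fold fall (log2 fold change -3.33, SE 0.29; adjusted p = 2.39e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; exact permutation p = 0.029, the smallest possible). YAP1, a transcriptional coactivator of the Hippo pathway (ENSG00000137693.13, chromosome 11, 102110461 to 102233423), was at 7.35 ± 3.56 CPM in siYAP1 (n = 3) against 95.1 ± 20.2 CPM in siCTRL (n = 4), a 12.9-fold fall (log2 fold change -3.69, SE 0.33; edgeR adjusted p = 2.95e-04; exact permutation p = 0.057, the smallest possible). In siHuR, YAP1 was at 57.9 ± 12 CPM (n = 4), 1.64-fold below siCTRL (log2 fold change -0.72, SE 0.26). This difference did not pass the edgeR threshold (adjusted p = 0.112; exact permutation p = 0.029), although all 4 siHuR libraries lay below all 4 siCTRL libraries. Its adjusted p ranged from 0.0251 to 0.354 over the alternatives, and the annotated 3' UTR of YAP1 contains the heptamer AATGGTT that is described with the siHuR falls. ELAVL1 in siYAP1 was at 185 ± 11.4 CPM (n = 3), with a log2 fold change of -0.25 (SE 0.28; edgeR adjusted p = 0.711).

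**Figure D1:**
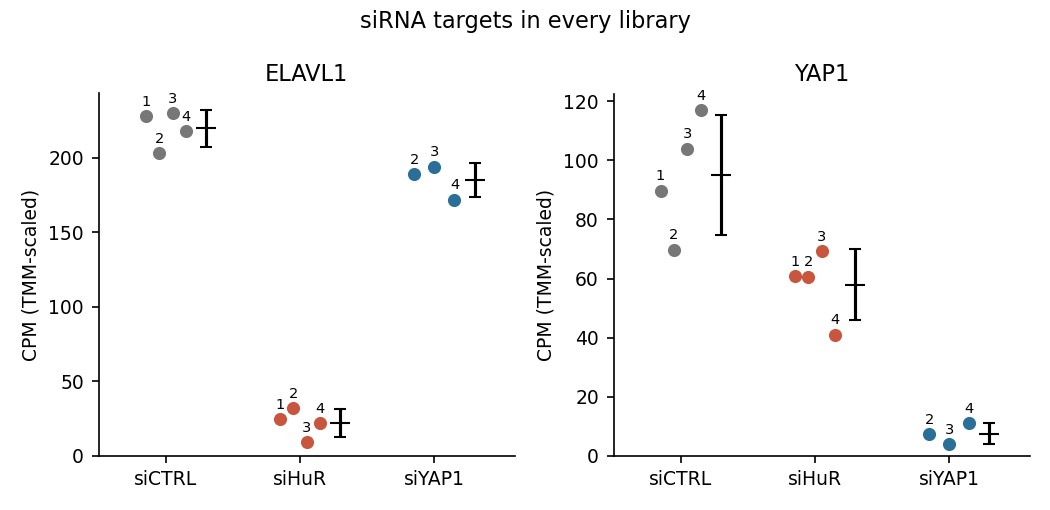
TMM-scaled CPM of ELAVL1 and YAP1 in each library, numbered by replicate, with the mean and SD of each group beside the points. ELAVL1 averaged 21.8 CPM in siHuR against 220 CPM in siCTRL, and YAP1 averaged 7.35 CPM in siYAP1, 57.9 CPM in siHuR and 95.1 CPM in siCTRL.

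The comparison of siHuR with siCTRL asks which mRNAs differ when HuR, an RNA-binding protein that binds U-rich and AU-rich sequences, is reduced. PSMD10, the proteasome assembly factor gankyrin (ENSG00000101843.18, chromosome X, 108084207 to 108091618), fell from 49.4 ± 4.65 to 4.41 ± 0.728 CPM (SD, n = 4 each), an 11.2-fold difference. RAD51AP1, a homologous recombination factor (chromosome 12, 4538798 to 4560048), fell 6.98-fold from 44.0 ± 3.83 CPM, and PLAUR, the urokinase receptor (chromosome 19, 43646095 to 43670547), fell 5.32-fold from 32.9 ± 9.56 CPM. PSKH1, a serine kinase gene (chromosome 16, 67893272 to 67929678), rose 3.78-fold from 25.1 ± 3.07 to 95.0 ± 20.6 CPM, and DBP, a circadian transcription factor (chromosome 19, 48630030 to 48637438), rose 3.63-fold from 11.6 ± 2.33 to 42.0 ± 8.45 CPM. In total 717 genes were higher and 927 lower in siHuR by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Upper-quartile scaling gave 949 higher and 893 lower.

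The other large falls in siHuR were in LRRC58 (6.95-fold), AMMECR1 (6.88-fold), the lipid flippase subunit TMEM30A (5.85-fold), BMT2 (5.53-fold), TOMM34 (5.25-fold) and CMTM6, a stabiliser of PD-L1 (5-fold). Of the 10 largest falls, ELAVL1 included, 8 were in genes with the heptamer AATGGTT or GTCGTAT in the annotated 3' UTR, all but ELAVL1 and PLAUR. Over all genes called lower, 36.9% of the 865 with a searched 3' UTR carried either word, against 12.4% of genes not called and 5.1% of genes called higher. After removal of genes found with either word, 613 were higher and 544 lower of 16075 genes, unsearched genes included, a restriction chosen after seeing the data. The other large rises were in the purinergic receptor P2RX6 (4.77-fold), the microtubule-associated protein MAP1A (4.16-fold), ZNF467 (3.70-fold), the sterol reductase TM7SF2 (3.50-fold), FAM107B (3.21-fold), YPEL3 (3.11-fold), the potassium channel KCNH3 (3.08-fold) and ISYNA1, which makes inositol phosphate (3.02-fold). The edgeR adjusted p of the 20 genes ranged from 6.05e-08 to 0.00443, and each kept its call when any 1 library was left out. The count of called genes fell to 893, 873 and 940 without siCTRL 1, siCTRL 3 and siCTRL 4, and was 2216 without siHuR 3 and siYAP1 3, a choice made after seeing the data.

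**Figure D2:**
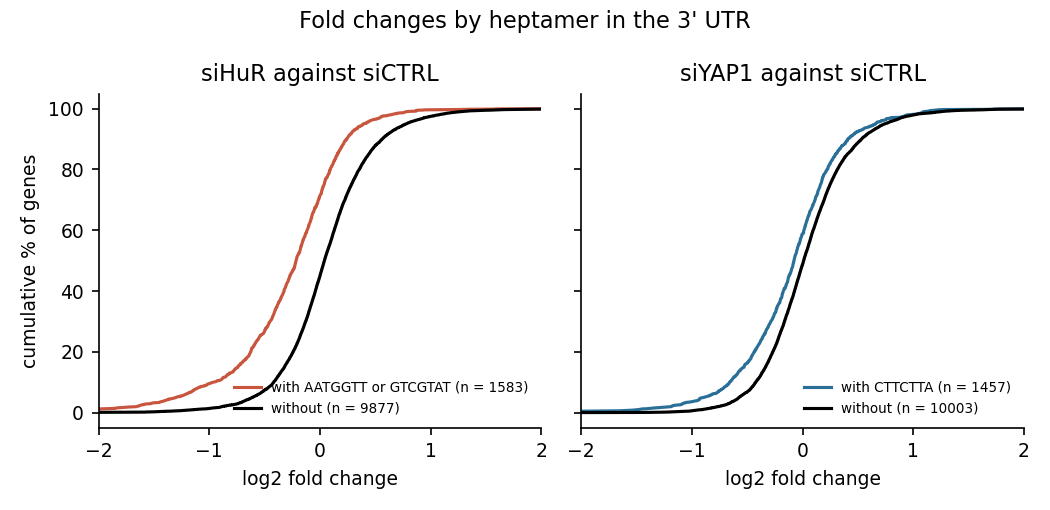
Cumulative percentage of genes (vertical axis) by log2 fold change (horizontal axis, shown from -2 to 2) in siHuR and in siYAP1 against siCTRL, for protein-coding genes with and without the named heptamers in the 3' UTR. The curve of genes with AATGGTT or GTCGTAT lies to the left in siHuR, and that of genes with CTTCTTA lies to the left in siYAP1.

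Many mitotic genes fell in siHuR. Of 36 members tested, 17 fell and 0 rose over all genes, and 27 fell adjusted over the list alone (camera adjusted p = 7.98e-17, adjusted p = 0.336 with an estimated correlation). ECT2, a cytokinesis exchange factor, fell 2.09-fold (log2 fold change -1.06, SE 0.15; edgeR adjusted p = 8.90e-04), the spindle checkpoint gene BUB3 1.77-fold (-0.82, SE 0.12; 8.71e-04) and PRC1, a midzone microtubule bundler with AATGGTT in its 3' UTR, 1.79-fold (-0.84, SE 0.13; 0.00178). Among 36 DNA repair genes, 3 fell and 0 rose, as many as when adjusted over the list alone, with RAD51AP1 among them; the camera adjusted p was 0.00679, and the adjusted p was 0.435 with an estimated correlation. The list lost its call without siHuR 4 (0.0789).

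Some inflammatory cytokines and chemokines fell in siHuR. Of 20 tested, 5 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.351 with an estimated correlation). The neutrophil chemokine CXCL8 fell 2.98-fold from 135 ± 20.1 CPM (SD, n = 4; edgeR adjusted p = 3.30e-04), LIF 2.29-fold (0.00105) and the granulocyte growth factor CSF3 4.99-fold (0.00283). Of 32 immediate early genes, 7 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.302 with an estimated correlation). The AP-1 genes JUN and FOSL1 fell 1.99-fold and 2.36-fold (edgeR adjusted p = 1.36e-04 and 0.00289), while JUND rose 1.72-fold (0.00227). Of 34 unfolded protein and ATF4 response genes, 7 fell and 0 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.351 with an estimated correlation). Its members with the smallest adjusted p, the disulfide isomerase PDIA6 (3.56-fold), the folate enzyme MTHFD2 (3.08-fold) and DNAJB9 (2.39-fold), all carried AATGGTT or GTCGTAT, and the 24 members without either word gave a camera adjusted p of 0.496. Of 28 p53 targets, 8 fell and 1 rose (10 and 5 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.351 with an estimated correlation), with TIGAR 2.22-fold and TRIAP1 2.21-fold lower, both with AATGGTT. Over the 23 members without the words the camera adjusted p was 0.367. Without siCTRL 1, siHuR 2, siHuR 3 or siHuR 4 this list lost its call (adjusted p up to 0.095).

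Some genes of cell adhesion and epithelial-mesenchymal transition also fell in siHuR. Of 20 epithelial-mesenchymal transition genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.00679, adjusted p = 0.252 with an estimated correlation). Among them were the epithelial junction genes OCLN (3.11-fold, with AATGGTT) and CLDN4 (1.90-fold), and the matrix gene TGFBI (1.85-fold). Of 34 integrin and focal adhesion genes, 6 fell and 2 rose (12 and 2 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.351 with an estimated correlation; 0.0759 at preset correlation without siHuR 4). The kindlin FERMT1 fell 2.72-fold, PXN 1.60-fold and ITGB4, with AATGGTT, 2.30-fold, and the kinase gene SRC rose 1.51-fold (edgeR adjusted p from 7.89e-04 to 0.00557).

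The lists named for HuR and for YAP also passed the list test in siHuR. Of 46 reported HuR target mRNAs, 8 fell and 5 rose (14 and 7 adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 0.0244, adjusted p = 0.435 with an estimated correlation). The urokinase gene PLAU fell 3.58-fold, the kinase gene PIM1 1.85-fold, and DNMT3B and CCNA2, both with AATGGTT, 2.01-fold and 2.27-fold. Without siHuR 4 the list's adjusted p was 0.0789, and over the 33 members without the words it was 0.0815. Of 23 ARE-binding and ELAVL family genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone): ELAVL1 itself, the splicing regulator CELF1 (1.99-fold) and HNRNPD (1.53-fold). The list gave a camera adjusted p of 0.0244, an adjusted p of 0.435 with an estimated correlation, and 0.21 at preset correlation without siHuR 4. Its median log2 fold change was -0.01. Since ELAVL1 is the siRNA target, its fall is part of this test, and the list was not tested without it. Of 18 YAP/TAZ target genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0244, adjusted p = 0.435 with an estimated correlation). NT5E, the ecto-nucleotidase CD73, fell 2.50-fold from 605 ± 66.6 to 242 ± 53.6 CPM (SD, n = 4 each; edgeR adjusted p = 4.47e-04). The receptor kinase AXL fell 2.92-fold, GADD45A 1.78-fold and LATS2 1.63-fold, the last pair with AATGGTT, but each lost its call without at least 6 of the 8 libraries in turn, with highest adjusted p of 0.0648, 0.116 and 0.146 without siCTRL 1. The log2 fold changes of CCN1, CCN2 and AMOTL2 were -0.54, -1.21 and -0.04 (edgeR adjusted p = 0.0662, 0.11 and 0.925). The list's call was lost without siCTRL 1 (0.0558), siCTRL 4 (0.0516) or siHuR 4 (0.0789).

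Mitochondrially encoded mRNAs had a median log2 fold change of 0.85 in siHuR, beside the mitochondrial share given above. None of the 13 passed edgeR's test over all genes or adjusted over the list alone, and MT-ND2 had the smallest adjusted p (0.0714). The list test gave a camera adjusted p of 0.00114 and an adjusted p of 0.506 with an estimated correlation. Interferon response genes had a median log2 fold change of 0.42 in siHuR. Of 39, 2 rose and 0 fell (also 2 and 0 adjusted over the list alone, camera adjusted p = 0.053, adjusted p = 0.798 with an estimated correlation), namely IRF1 (1.80-fold) and STAT2 (1.49-fold). IRF1 lost its call in 5 and STAT2 in 6 of the 8 fits that left out 1 library, with adjusted p up to 0.0815 and 0.101 without siCTRL 1.

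The comparison of siYAP1 with siCTRL asks which mRNAs differ when YAP1 is reduced. OSTM1, a lysosomal chloride transport subunit (ENSG00000081087.14, chromosome 6, 108041409 to 108165854), fell from 71.2 ± 4.88 CPM (SD, n = 4) to 12 ± 2.27 CPM (n = 3), a 5.94-fold difference. TNFRSF21, death receptor 6 (chromosome 6, 47231532 to 47309905), fell 6.95-fold to 1.45 ± 0.606 CPM, and ARL6IP1, an endoplasmic reticulum shaping protein (chromosome 16, 18791667 to 18801678), fell 4.08-fold from 273 ± 19.8 to 67.1 ± 11.6 CPM. MAP1A (chromosome 15, 43510958 to 43531620) rose 4.22-fold from 3.27 ± 1.70 to 13.8 ± 2.74 CPM, and CA11 (chromosome 19, 48637942 to 48646312) rose 3.38-fold from 3.95 ± 1.02 to 13.4 ± 2.21 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 367 genes were higher and 452 lower in siYAP1. Upper-quartile scaling gave 494 higher and 391 lower, and scaling by library size gave 468 and 367.

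Further large falls in siYAP1 were in CSF3 (6.13-fold), the kinase gene UHMK1 (5.25-fold), LYRM1 (4.37-fold), the antiproliferative gene BTG3 (3.79-fold), the tight junction gene CLDN12 (3.56-fold) and PLAUR (3.53-fold). Of the 10 largest falls, YAP1 included, 8 were in genes with the heptamer CTTCTTA in the annotated 3' UTR, all but BTG3 and PLAUR. This word was found in 31.2% of the 433 searched genes called lower, 12% of genes not called and 10.5% of genes called higher. After removal of genes found with it, 295 were higher and 282 lower of 16201 genes, unsearched genes included, a restriction chosen after seeing the data. Further rises were in PACSIN1 (3.28-fold), ZFHX2 (3.27-fold), the synaptic scaffold gene BSN (3.2-fold), ZNF467 (3.17-fold), P2RX6 (3.30-fold), the lipoprotein receptor LRP1 (3.06-fold) and TM7SF2 (2.94-fold). EIF3CL had the largest fitted rise, 8.42-fold, but its level in siYAP1 was 102 ± 133 CPM (n = 3), reads can be split with its near-identical paralog EIF3C, and its adjusted p was 0.0466 without and 0.386 with the replicate block. It lost its call in 6 of the 7 fits that left out 1 library (up to 0.169 without siYAP1 2). The edgeR adjusted p of the 20 genes ranged from 3.94e-05 to 0.0466. LRP1 lost its call without siYAP1 4 (0.0766), P2RX6 without siCTRL 1, siCTRL 3 or siYAP1 4 (up to 0.0821), and TM7SF2 without siCTRL 1, siCTRL 3, siCTRL 4, siYAP1 3 or siYAP1 4 (up to 0.0911). The count of called genes was 208 without siYAP1 4, 333 without siYAP1 3, and 236, 213 and 396 without siCTRL 1, 3 and 4.

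Some DNA replication and mitotic genes fell in siYAP1. Of 36 replication genes, 9 fell and 0 rose (20 and 0 adjusted over the list alone, camera adjusted p = 4.28e-15, adjusted p = 0.184 with an estimated correlation). CDC45, part of the replicative helicase, fell 2.58-fold (log2 fold change -1.37, SE 0.15; edgeR adjusted p = 0.00133), and RRM2, a ribonucleotide reductase subunit, fell 2.15-fold from 450 ± 61.1 to 209 ± 39.1 CPM (0.0101, and 0.0645 without siYAP1 4); both carried CTTCTTA. The helicase gene MCM7, without the word, fell 1.58-fold (0.0136), and lost its call without siCTRL 1, siCTRL 3 or siYAP1 4 (up to 0.0816). Of 36 mitotic genes, 11 fell and 0 rose (23 and 0 adjusted over the list alone, camera adjusted p = 5.19e-16, adjusted p = 0.184 with an estimated correlation). The ubiquitin-conjugating enzyme gene UBE2C fell 1.97-fold (-0.98, SE 0.16; 0.00492), and BUB3, with CTTCTTA, fell 1.58-fold (0.0138), losing its call without siCTRL 3, siYAP1 3 or siYAP1 4 (up to 0.0821). Of 36 DNA repair genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 2.65e-04, adjusted p = 0.402 with an estimated correlation). They were RAD54L (1.62-fold), XRCC2 (1.56-fold), RAD51AP1 (1.76-fold) and FANCA (1.40-fold), and each lost its call in at least 5 of the 7 fits that left out 1 library (adjusted p up to 0.12, 0.124, 0.12 and 0.0911 without siYAP1 4).

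Some cytokine, immediate early and stress response genes fell in siYAP1 as well. Of 20 cytokines and chemokines, 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.184 with an estimated correlation): CSF3, CXCL8 (2.51-fold), CXCL1 (2.35-fold) and LIF (1.86-fold). CXCL1 lost its call without siCTRL 3 or siYAP1 3 (0.0523), and LIF in 5 of 7 such fits (0.0735 without siYAP1 3). Of 32 immediate early genes, 6 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 2.54e-06, adjusted p = 0.166 with an estimated correlation), with JUN 1.78-fold (edgeR adjusted p = 0.00331), the zinc finger gene EGR1 2.42-fold (0.00609) and the phosphatase gene DUSP5 2.16-fold lower (0.00711). Of 34 unfolded protein and ATF4 response genes, 3 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 2.71e-06, adjusted p = 0.184 with an estimated correlation). These were MANF (1.71-fold), SDF2L1 (1.61-fold) and the amino acid transporter subunit SLC3A2 (1.65-fold), which lost their calls in 2, 4 and 6 of 7 such fits (up to 0.0685, 0.0965 and 0.152 without siYAP1 4). Of 35 apoptosis regulators, 4 fell and 1 rose (14 and 2 adjusted over the list alone, camera adjusted p = 2.09e-04, adjusted p = 0.184 with an estimated correlation). The anti-apoptotic gene MCL1, which carries CTTCTTA and is also on the HuR target list, fell 2.91-fold from 288 ± 46.6 to 99.2 ± 0.761 CPM (edgeR adjusted p = 0.00142). The pro-apoptotic gene BMF rose 4.09-fold from 0.355 ± 0.134 CPM (0.00603).

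Of 18 YAP/TAZ target genes in siYAP1, 2 fell and 1 rose (4 and 1 adjusted over the list alone), with a median log2 fold change of -0.07 (camera adjusted p = 0.334, adjusted p = 0.758 with an estimated correlation). NT5E fell 1.99-fold from 605 ± 66.6 CPM (SD, n = 4) to 304 ± 47.3 CPM (n = 3; edgeR adjusted p = 0.0115), and lost its call without siYAP1 4 (0.0725). CCN1, a matricellular protein, fell 1.76-fold (0.0281) and RBMS3 rose 2.22-fold (0.0391), each losing its call in 6 of the 7 fits that left out 1 library (up to 0.0971 and 0.164 without siYAP1 3). GADD45A had a log2 fold change of -0.90 (0.0704; 0.014 with the replicate block). The log2 fold changes of CCN2, AXL, AMOTL2, F3, FJX1, NUAK2 and CRIM1 were -1.48, -0.43, -0.13, -0.47, -0.26, -0.48 and -0.01, and those of MYOF, LATS2, ASAP1, CCDC80, DOCK5, PTPN14 and ARHGEF17 were 0.23, 0.08, 0.24, 0.22, 0.38, 0.46 and 0.32. None of these 14 genes passed edgeR's test (adjusted p from 0.111 to 0.99). CCN2 was at 1.88 ± 1.21 CPM in siYAP1 and 5.24 ± 1.78 CPM in siCTRL. Of 46 HuR target mRNAs, 6 fell and 1 rose in siYAP1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.322 with an estimated correlation), with DCK 2.38-fold lower and IDH1 1.89-fold higher. YAP1 itself is among the 6, and over the 38 members without CTTCTTA the camera adjusted p was 0.121.

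Mitochondrially encoded mRNAs had a median log2 fold change of 1.10 in siYAP1. None of the 13 passed edgeR's test over all genes, and 12 passed it adjusted over the list alone (camera adjusted p = 9.19e-07, adjusted p = 0.402 with an estimated correlation); with the replicate block MT-ND1, MT-ND4 and MT-CO3 passed it over all genes (0.0349, 0.0297 and 0.0285). Of 39 interferon response genes, 1 rose and 0 fell over all genes, and none did adjusted over the list alone (camera adjusted p = 1.52e-04, adjusted p = 0.6 with an estimated correlation). DTX3L rose 1.90-fold (edgeR adjusted p = 0.0402), losing its call in 6 of 7 fits that left out 1 library (up to 0.159 without siYAP1 3), while PARP9 and IFI35 passed with the replicate block only (0.00468 and 0.0315; 0.0608 and 0.11 without it). Per library, the median log2 deviation of the interferon genes from their mean lay between -0.85 and -0.32 in libraries numbered 1 and 2 and between 0.04 and 0.83 in those numbered 3 and 4, in all groups. None of 52 cytosolic ribosomal protein genes, many of which share sequence with pseudogenes, passed either adjustment in siYAP1 (median log2 fold change -0.12, camera adjusted p = 0.00705, adjusted p = 0.758 with an estimated correlation; 0.0519 with the replicate block; 0.0681 without siCTRL 3). The fatty acid synthesis list missed the threshold without the replicate block and passed with it (camera adjusted p = 0.0551 and 0.0376, and 0.0401 without the block over the 19 members without CTTCTTA, adjusted p = 0.595 with an estimated correlation), with 2 of 20 genes higher and 0 lower, also adjusted over the list alone.

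**Figure D3:**
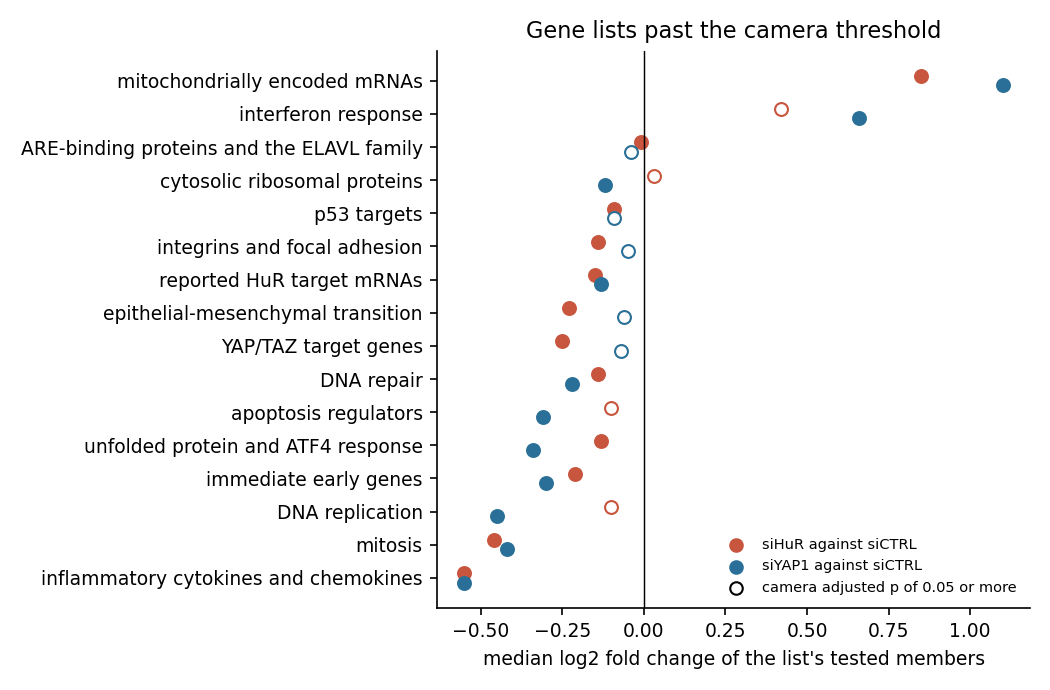
Median log2 fold change of each gene list past the camera threshold in siHuR (red) or siYAP1 (blue) against siCTRL, with open circles where the adjusted p was 0.05 or more. The mitochondrially encoded mRNAs had medians of 0.85 and 1.10, and the mitotic genes of -0.46 and -0.42.

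**Figure D4:**
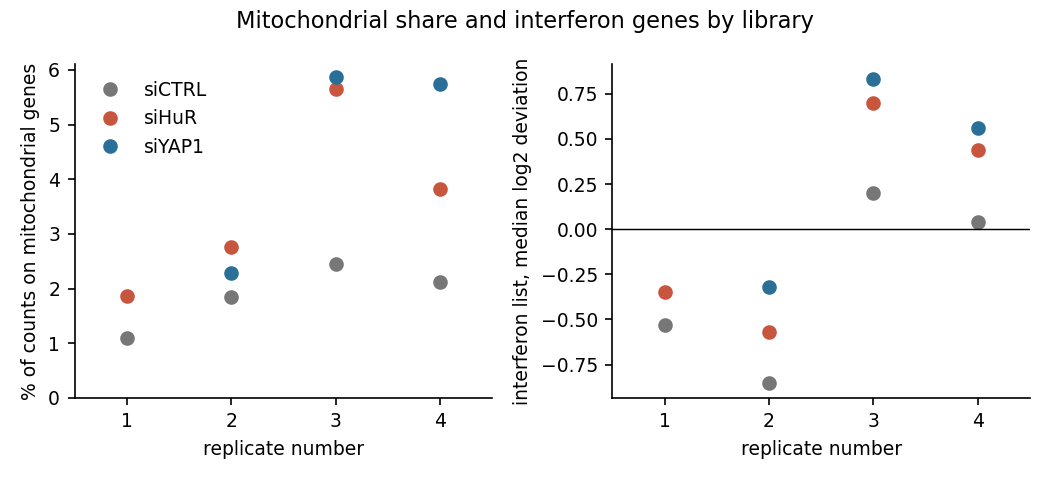
Percentage of counts on mitochondrial genes (left) and median log2 deviation of 39 interferon response genes from their mean over all libraries (right), for each library by replicate number. Interferon values were below 0 in libraries 1 and 2 and above 0 in libraries 3 and 4, and within each number siHuR and siYAP1 lay above siCTRL in both plots.

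The log2 fold changes of siHuR and siYAP1 against siCTRL correlated across 17658 genes with Pearson r = 0.54 and Spearman rho = 0.52, where genes are not independent replicates. Simulated unchanged groups against the same controls gave a mean r of 0.46, and dividing the controls between the comparisons gave 0.14 to 0.40. The covariance was 0.168, against 0.0912 in the simulations, a difference of 0.0763, and was 0.0636 to 0.148 with divided controls. The simulations held no effect of the replicate number, so this difference can include such effects. With the replicate block r was 0.50, the covariance 0.162, and 599 genes were called in the same direction. The block fit left out siCTRL 1 and siHuR 1 for siYAP1 but not for siHuR, so these fold changes rest on different libraries. In both comparisons 198 genes were higher and 172 lower, where independent lists would share 14.9 and 23.7. Simulated unchanged groups shared at most 1, but they had hardly any called genes to share. Their count therefore does not show how many shared calls come from the common controls. With divided controls the numbers were 7 to 30 and 6 to 32. The genes most firmly shared were BTG3 (2.57-fold lower in siHuR, 3.79-fold in siYAP1), CLDN12 (4.21-fold and 3.56-fold lower, with both AATGGTT and CTTCTTA), YPEL2 (2.82-fold and 3.69-fold higher), ZMYM3 (1.61-fold and 1.85-fold higher) and TUBB4A, which has close paralogs (1.70-fold and 2.05-fold higher). Both genes called in opposite directions were TUBA1A, a tubulin gene with close paralogs (1.63-fold lower in siHuR, 2.39-fold higher in siYAP1; call lost in siHuR without siCTRL 3, 0.0547), and CPOX, a heme synthesis gene (1.57-fold higher and 1.98-fold lower). CPOX lost its call in 7 of 8 such fits of siHuR (up to 0.119 without siHuR 1) and in siYAP1 without siCTRL 1, siYAP1 3 or siYAP1 4 (up to 0.0685). The shared count of 370 was 105, 90, 166, 188 and 106 without siCTRL 1, siCTRL 3, siCTRL 4, siYAP1 3 and siYAP1 4.

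The direct comparison of siHuR with siYAP1 tests the difference between the knockdowns. Besides ELAVL1 (8.47-fold lower in siHuR) and YAP1 (7.87-fold higher), PSMD10 was 8.64-fold lower in siHuR at 4.41 ± 0.728 CPM (SD, n = 4) against 38.1 ± 3.15 CPM (n = 3). BMT2 was 6.66-fold, TOMM34 4.97-fold and the transporter gene ABCC4 4.97-fold lower in siHuR, while LYRM1 was 5-fold, ARL6IP1 4.75-fold, TNFRSF21 4.39-fold and OSTM1 3.55-fold higher. All of these except ELAVL1 carried one of the 3 heptamers. In total 283 genes were higher and 457 lower in siHuR than in siYAP1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After removal of genes found with any of the words, unsearched genes included, 67 were higher and 96 lower, a restriction chosen after seeing the data. The count was 378, 364 and 334 without siHuR 1, siYAP1 3 and siYAP1 4, 481 without both siHuR 3 and siYAP1 3, and 282 when only these groups were fitted.

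Some replication genes were higher in siHuR than in siYAP1, with 6 of 36 higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 2.46e-09, adjusted p = 0.746 with an estimated correlation). CDC45 was 2.25-fold and RRM2 2.20-fold higher (edgeR adjusted p = 7.39e-04 and 0.00585), and E2F1, without the words, was 2.23-fold higher (0.0122), losing its call without siHuR 1, siYAP1 3 or siYAP1 4 (up to 0.0578). Over the 30 replication genes without the words, 1 was called higher and 0 lower, with a camera adjusted p of 3.56e-08. Of 20 epithelial-mesenchymal transition genes, OCLN alone passed over all genes, 2.68-fold lower (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0274, adjusted p = 0.33 with an estimated correlation), and the list lost its call without siHuR 1 (0.0712) or siYAP1 3. With the replicate block CLDN4 and KRT19 passed as well (0.0127 and 0.00577; 0.0638 and 0.0937 without it). Of 34 integrin and focal adhesion genes, 2 were lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.0427, adjusted p = 0.844 with an estimated correlation; up to 0.225 without siHuR 4), namely ITGB4 (2.83-fold) and CAV1 (1.91-fold; 0.0497, and up to 0.176 without siYAP1 4). LIMS1 passed with the block only (0.0473; 0.0725 without it). Over the 29 integrin and adhesion genes without the words the list did not pass (camera adjusted p = 0.0704). The unfolded protein and ATF4 response list, with 4 of 34 genes higher and 3 lower (6 and 4 adjusted over the list alone), gave a camera adjusted p of 0.63 and an adjusted p of 0.941 with an estimated correlation. Over its 23 members without the words the camera adjusted p was 6.14e-06, with a median log2 fold change of 0.28. The ribosomal protein list had a median log2 fold change of 0.17 and a camera adjusted p of 0.00636, with 0 of 52 genes called by either adjustment. Its camera adjusted p was 0.941 with an estimated correlation, and 0.292 at preset correlation without siHuR 4. The oxidative phosphorylation list had a median log2 fold change of 0.25 and a camera adjusted p of 0.0427 (0.941 with an estimated correlation, 0.0611 with the block, up to 0.347 without siHuR 4). The only member of 39 called by either adjustment was SDHC, which carries AATGGTT. It was 1.92-fold lower, against the direction of the list. Of the YAP/TAZ targets none passed over all genes or adjusted over the list alone (camera adjusted p = 0.352), and LATS2 and AXL passed with the block only (0.0391 and 0.0173; 0.0591 and 0.146 without it). Of the HuR targets 4 were higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.762), with YAP1 itself on the list, MCL1 2.86-fold higher and CTNNB1 1.96-fold lower, the last with AATGGTT, and of the interferon genes DTX3L alone passed, 1.95-fold lower (camera adjusted p = 0.3; call lost in 5 of 7 fits that left out 1 library, up to 0.143 without siYAP1 4).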

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

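The test of sequencing depth in siYAP1 3 was chosen after its result was seen, and those of gene length and GC content were written down before.

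The library siYAP1 3 stood apart from the other 10. It lay at 107.2 on the first principal component (34.6% of variance), where siHuR 3 at 51.2 came next, and it had 20639 genes with a count against 23925 to 28510. The gene ENSG00000277105.1, which is not in the reference used and so has no name or position here, took 13.2% of its TPM, against 2.08% to 4.53% in the other libraries. The tables argue against gene length, GC content and lower depth as the source. The library's log2 deviation from its group mean had a Spearman rho of 0.09 with gene length (-0.458 to 0.323 in the others) and of -0.15 with GC content (-0.284 to 0.513), and its total of 42.0 M counts was within the range of the others. A difference in RNA quality or in handling stays open and was not tested, and no biological explanation was tested. Among the other libraries, the extremes of -0.458 for length and 0.513 for GC content were both from siHuR 4. Without siHuR 4, 6 lists passed in siHuR against siCTRL in place of 12. Whether length or GC content bears on those calls was not tested.

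Among the named genes and lists, 17 of 362 sets of 4 libraries had 1 library farther from the other 3 than Dixon's 95% critical value, where chance gives about 1 in 20. In siCTRL, FAM107B was at 26.4 CPM in siCTRL 2 against 13.2 to 14.5 CPM (ratio 0.9), JUN at 213 CPM in siCTRL 2 against 251 to 258 CPM (0.839), and UQCRH at 199 CPM in siCTRL 4 against 229 to 232 CPM (0.911). In siCTRL 1, IDH1 was at 39.4 CPM against 54.2 to 56.6 CPM (0.862), LYRM1 at 14.3 CPM against 16.4 to 16.6 CPM (0.904) and ZMYM3 at 46.9 CPM against 54.6 to 55.7 CPM (0.875). The median log2 deviation of 3 lists also stood apart in siCTRL. It was 0.263 in siCTRL 3 against 0.0713 to 0.103 for epithelial-mesenchymal transition (0.836), 0.0135 in siCTRL 2 against 0.195 to 0.223 for DNA repair (0.865), and 0.467 in siCTRL 2 against -0.509 to -0.348 for pancreatic markers (0.835). In siHuR 4, CA11 was at 16.1 CPM against 8.37 to 9.24 CPM (0.888), ECT2 at 111 CPM against 161 to 165 CPM (0.932) and EGR1 at 52.3 CPM against 33.6 to 36.7 CPM (0.832). In siHuR 2, CLDN4 was at 41 CPM against 24 to 26.8 CPM (0.833) and PSMD10 at 5.5 CPM against 4 to 4.09 CPM (0.935). In siHuR 3, PLK3 was at 4.4 CPM against 7.8 to 8.34 CPM (0.864) and YPEL2 at 3.21 CPM against 4.16 to 4.21 CPM (0.952), and NUAK2 was at 14.8 CPM in siHuR 1 against 9.66 to 10.3 CPM (0.88).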

How the results depend on the processing

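The fits without siHuR 3 and siYAP1 3, those without genes carrying the 3' UTR heptamers, and the SD of 0.0705 over fits without 1 library that judged shifts of the correlation were chosen after seeing the data.

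ELAVL1 fell in siHuR and YAP1 fell in siYAP1 under every alternative run, with log2 fold changes of -3.58 to -3.09 and -4.10 to -3.17 and adjusted p of at most 2.50e-04 and 0.00571. ELAVL1 in siYAP1 stayed above 0.05 (0.195 to 0.838). YAP1 in siHuR passed 0.05 in 3 alternatives, DESeq2 (log2 fold change -0.73), a fit of only the 2 groups (-0.73) and the fit without siHuR 3 and siYAP1 3 (-0.83). Its adjusted p ranged from 0.0251 to 0.354, and the cause was not tested.

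The count for siHuR against siCTRL, 1644, was 2499 with DESeq2, 823 and 804 with limma on log2(TPM + 1) and log2(TPM + 0.1), and 3326 with the replicate block. It was 539 at an absolute log2 fold change of at least 1 and 686 at an adjusted p under 0.01. For siYAP1 against siCTRL, 819 became 1688, 275 and 267 by those 3 tests, 401 with the transcript length offset, and 259 and 157 at the stricter thresholds. For siHuR against siYAP1, 740 became 1469, 264 and 265, 381 with the offset, 282 with only the 2 groups fitted, 481 without siHuR 3 and siYAP1 3, 163 without genes carrying the heptamers, and 273 and 280 at the stricter thresholds. The stricter thresholds call fewer genes by construction, and for the rest the cause was not tested. Leaving out 1 library gave 873 to 1636 (893, 873 and 940 without siCTRL 1, 3 and 4), 208 to 644 (236, 213, 396, 333 and 208 without siCTRL 1, 3, 4, siYAP1 3 and siYAP1 4) and 334 to 964 (378, 364 and 334 without siHuR 1, siYAP1 3 and siYAP1 4). Other scalings, voom, other filters and the fit that was not robust kept each count within 1.5 times, and no scaling moved the median gene by more than 0.084.

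The correlation of the 2 knockdowns, 0.54, was 0.46 with no filter on low counts and 0.66 over genes called in either comparison. With the controls divided so that siHuR met siCTRL 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, or 3 and 4, it was 0.32, 0.25, 0.23, 0.40, 0.36 and 0.14, and the shared calls, 370, were 60, 13, 27, 56, 60 and 46. Shared calls were also 169 with the length offset, 599 with the block and 96 at an absolute log2 fold change of at least 1. Without 1 library the correlation was 0.39 (siYAP1 2) to 0.64 (siCTRL 2), with 0.42 and 0.46 without siYAP1 4 and siHuR 3, and the shared calls were 90 to 386 (105, 90, 166, 188 and 106 without siCTRL 1, 3, 4, siYAP1 3 and siYAP1 4). The cause was not tested.

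With an estimated inter-gene correlation, camera called 0 lists in each comparison, against 12, 11 and 5. In siHuR against siCTRL 6 lists passed with the stricter filter, and in siHuR against siYAP1 2 passed with it and 2 with fry. Without 1 library the counts were 6 (siHuR 4) to 16, 10 to 14, and 2 to 9 (3, 3, 2, 8 and 9 without siHuR 1, siYAP1 3, siHuR 4, siYAP1 2 and siHuR 3). In siHuR the YAP/TAZ list, 0.0244, gave 0.0739 with the stricter filter, 0.435 with an estimated correlation and 0.0595 with fry, which tests a list against no change and not against other genes, and the HuR target list, also 0.0244, gave 0.0739, 0.435 and 0.0815 over genes without the heptamers. Without 1 library they ranged from 0.00621 to 0.0789 and from 0.00807 to 0.0789, both highest without siHuR 4. Over genes without the heptamers, TGF-beta targets in siHuR (0.0326) and p53 targets in siYAP1 (0.0157) passed. The cause was not tested.

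A few log2 fold changes near 0 that passed no test changed sign, and the cause was not tested. AMOTL2 in siHuR (-0.04) was 0.00 by upper quartile. In siYAP1, LATS2 (0.08) was -0.09 and -0.10 by limma on TPM and -0.07 with the length offset, and DOCK5 (0.38) was -0.03 and -0.05 on TPM. CRIM1 (-0.01) was 0.05 by upper quartile, 0.04 by library size, 0.03 with the stricter filter, 0.09 with the block and 0.05 without siHuR 3 and siYAP1 3. AMOTL2 in siHuR against siYAP1 (0.09) was -0.02 with the length offset and -0.02 with the block. Without 1 library, AMOTL2 in siHuR ranged from -0.18 to 0.05, LATS2 in siYAP1 from -0.04 to 0.19, CRIM1 from -0.19 to 0.10 and CCDC80 (0.22) from -0.05 to 0.34, and in siHuR against siYAP1 CCN2 (0.26) ranged from -0.20 to 0.67 and AMOTL2 from -0.05 to 0.16.

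Of the named genes past 0.05, 57 of 68 in siHuR, 31 of 57 in siYAP1 and 18 of 22 in siHuR against siYAP1 kept their call whichever library was left out. In the paired comparisons, the block fit also left out siCTRL 1 and siHuR 1. It changed the calls printed beside their results and that of SLC7A5 in siYAP1 (0.0538 without and 0.0211 with the block), and no other call of a named gene or a list. In siHuR against siCTRL, where same-numbered libraries correlated at 0.26, 0.50, 0.26 and -0.01 and 3 of 4 matched best with their own number, the numbers were not taken to pair the libraries. There the block brought 9 named genes under 0.05, among them CCN1 (0.00493), CCN2 (0.0307) and MT-ND2 (0.00236), took the ARE-binding list above it (0.0627), and brought the interferon (9.19e-04), NRF2 (0.0342), apoptosis (0.0336) and TGF-beta (0.0304) lists under it. No alternative varied depth. In the simulated data set, at the depth of these libraries, 14.9% of 1.5-fold and 92.4% of 4-fold changes in siHuR were recovered. Genes below the count filter, ANKRD1 among them, were not tested.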

Other observations

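The heptamer tests and the counts of other divisions of the libraries were chosen after their results were seen, and the test of U-rich 3' UTRs was written down before.

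Gene lists that passed camera's test in neither comparison with siCTRL are given here as values. For NRF2 and oxidative stress, 5 of 29 genes were higher and 1 lower in siHuR over all genes, 7 and 2 adjusted over the list alone (camera adjusted p = 0.053, adjusted p = 0.435 with an estimated correlation). In siYAP1 the numbers were 1 and 1, and 3 and 3 adjusted over the list alone (0.575, and 0.816 with an estimated correlation). TGF-beta targets gave 1 and 4 of 22 in siHuR, 3 and 6 adjusted over the list alone (0.0778, and 0.435 with an estimated correlation), and 0 and 1 in siYAP1, 1 and 2 adjusted over the list alone (0.39, and 0.729 with an estimated correlation). Hippo pathway components gave 2 and 3 of 31 in siHuR, 3 and 4 adjusted over the list alone (0.122, and 0.796 with an estimated correlation), and 0 and 1 in siYAP1 by both adjustments (0.489, and 0.837 with an estimated correlation). The 1 Hippo gene lower in siYAP1 was YAP1, the siRNA target, so its fall is part of this test. For hypoxia response 0 and 2 of 19 passed in siHuR, also adjusted over the list alone (0.194, and 0.435 with an estimated correlation), and 0 and 0 in siYAP1, 1 and 4 adjusted over the list alone (0.357, and 0.595 with an estimated correlation). For glycolysis 0 and 4 of 20 passed in siHuR, 2 and 4 adjusted over the list alone (0.223, and 0.637 with an estimated correlation), and 0 and 3 in siYAP1, 1 and 4 adjusted over the list alone (0.134, and 0.6 with an estimated correlation). Cholesterol synthesis gave 1 and 3 of 23 in siHuR, also adjusted over the list alone (0.706, and 0.918 with an estimated correlation), and 1 and 0 in siYAP1, 1 and 2 adjusted over the list alone (0.543, and 0.837 with an estimated correlation).

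Oxidative phosphorylation gave 1 higher and 1 lower of 39 genes in siHuR, 0 and 1 adjusted over the list alone (camera adjusted p = 0.706, adjusted p = 0.918 with an estimated correlation), and none in siYAP1 by either adjustment (0.0714, and 0.758 with an estimated correlation). Replication-dependent histones gave 1 and 0 of 13 in siHuR by both adjustments (0.706, and 0.918 with an estimated correlation) and none in siYAP1 (0.949, and 0.961 with an estimated correlation). Fibroblast markers gave 0 and 1 of 7 in siHuR, 1 and 1 adjusted over the list alone (0.712, and 0.904 with an estimated correlation), and none in siYAP1 (0.715, and 0.816 with an estimated correlation). Macrophage and leukocyte markers gave 1 and 0 of 5 in siHuR by both adjustments (0.857, and 0.918 with an estimated correlation) and 1 and 0 in siYAP1, 1 and 2 adjusted over the list alone (0.952, and 0.961 with an estimated correlation). Pancreatic acinar and endocrine markers gave 0 of 2 in siHuR, 1 higher adjusted over the list alone (0.306, and 0.637 with an estimated correlation), and none in siYAP1 (0.736, and 0.837 with an estimated correlation). Fatty acid synthesis gave 3 and 1 of 20 in siHuR, 3 and 3 adjusted over the list alone (0.993, and 0.996 with an estimated correlation).

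Some lists passed in 1 comparison with siCTRL and not in the other, and whether the knockdowns differ for them is answered only by their direct comparison. In siHuR, apoptosis regulators gave 1 higher and 6 lower of 35, 4 and 10 adjusted over the list alone (camera adjusted p = 0.053, adjusted p = 0.435 with an estimated correlation). DNA replication gave 1 and 2 of 36, 0 and 2 adjusted over the list alone (0.218, and 0.838 with an estimated correlation), and ribosomal proteins none of 52 (0.706, and 0.94 with an estimated correlation). In siYAP1, p53 targets gave 2 and 4 of 28, 3 and 9 adjusted over the list alone (0.0859, and 0.402 with an estimated correlation), and ARE-binding genes gave 0 and 2 of 23, 0 and 3 adjusted over the list alone (0.177, and 0.748 with an estimated correlation). Integrin and focal adhesion genes gave 1 and 2 of 34, 2 and 4 adjusted over the list alone (0.797, and 0.882 with an estimated correlation), and epithelial-mesenchymal transition genes none of 20 (0.736, and 0.816 with an estimated correlation). In siHuR against siYAP1, apoptosis regulators, p53 targets and ARE-binding genes did not pass (camera adjusted p = 0.3, 0.762 and 0.524). With an estimated correlation the adjusted p was 0.941 for each. Over all genes, 1 and 1, 2 and 4, and 1 and 2 of their members were higher and lower.

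Genes with AATGGTT in the 3' UTR fell in siHuR. Over 1493 such genes the shift in log2 fold change was -0.221 (SE 0.014) with 3' UTR length, GC content and expression fitted, which argues against these as the whole source, and it was -0.013 in siYAP1. The word was picked from these libraries, where its shift was -0.21 ± 0.03 per siHuR library (SD, n = 4) and 0.00 ± 0.02 in siCTRL (n = 4). In siHuR against siYAP1 the shift of genes with TTTTTTT was -0.004 with 3' UTR length, GC content and expression fitted, and -0.13 unfitted. For genes with AATGGTT these values were -0.208 and -0.316. This argues against loss of HuR from U-rich 3' UTRs as the source of the AATGGTT shift. Whether U-rich mRNAs fell is not decided, since the fitted length and GC content overlap with U-richness. For genes with the AU-rich word TATTTAT the fitted shift was -0.048 in siHuR and -0.053 in siYAP1. In siHuR against siYAP1 it was 0.004 fitted and -0.107 unfitted. A candidate explanation of the AATGGTT shift is silencing of mRNAs that match a seed of the siHuR reagent. AATGGTT also ranked 1 of 16163 words in replicates 1 and 2 alone (-0.194), and gave -0.234 in replicates 3 and 4. All siHuR libraries had both the siRNA and the loss of ELAVL1, so this recurrence does not separate a seed effect from loss of the target. The siRNA sequences are not given in the sources used here. The longest ELAVL1 transcript holds 1 copy each of AATGGTT and GTCGTAT, where chance gives at least 1 copy of any single word in 30.7% of transcripts of that length.

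Genes with CTTCTTA in the 3' UTR fell in siYAP1. The shift over 1457 genes was -0.152 (SE 0.013) with 3' UTR length, GC content and expression fitted, which argues against these as the whole source, and it was 0.011 in siHuR. The word was picked from these libraries, where its shift was -0.15 ± 0.01 per siYAP1 library (SD, n = 3) and 0.00 ± 0.01 in siCTRL (n = 4). A candidate explanation is silencing of mRNAs that match a seed of the siYAP1 reagent. CTTCTTA also ranked 1 in replicate 2 alone (-0.127), and gave -0.159 in replicate 4 alone. All siYAP1 libraries had both the siRNA and the loss of YAP1, so this recurrence does not separate a seed effect from loss of the target. The longest YAP1 transcript holds 2 copies of CTTCTTA (chance of at least 1 copy 28.1%), and a second siRNA of another sequence for each target would separate seed effects from loss of the target.

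The counts of called genes were compared with other divisions of the same libraries into groups of the same sizes, using fits of the 2 groups alone. For siHuR against siCTRL, 1 of 35 divisions, the real one, gave as many as 1629 genes, and the highest other gave 32 (libraries 1 and 2 against 3 and 4). For siYAP1 against siCTRL, 1 of 35 gave as many as 1021, and the highest other gave 31 (siCTRL 1, siCTRL 2 and siYAP1 2 against the rest). For siHuR against siYAP1, 1 of 35 gave as many as 282, and the highest other gave 3. For siHuR against siCTRL, 1 of 35 is a share under 0.05 only if the libraries can be exchanged freely. What the replicate numbers mark is not known. If they pair these libraries, only 8 of the 35 divisions part every pair, and chance division is not excluded. In the other comparisons, where the numbers pair the libraries, only 8 of the 35 divisions part every pair, too few for a share under 0.05, and those other than the real one called 0 genes.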
